A study of Mus musculus with 8 samples.

How the data were processed

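RAW264.7 macrophages were untreated or treated with TBP, TCP or TIP at 100 µM for 24 h. Per the labels' protocols, RNA was immunoprecipitated with an anti-m6A antibody, fragments of 40 to 60 nt were selected on a gel, and libraries were made by poly(A) tailing, reverse transcription and PCR. The series has 8 samples, 4 immunoprecipitated and 4 input, with 1 of each per condition. The 4 peak lists, 1 per immunoprecipitated library, were analysed here.

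The submitters' processing notes name Trim Galore 0.6.5, HISAT2 2.1.0, StringTie 2.1.4, DESeq2 1.30.1, FastQC 0.11.9, Picard 2.23.5, SAMtools 1.9, ChIPseeker 1.26, HOMER 4.11 and deepTools 3.5.0, with no role or order, and the builds GRCm38 and mm10. The peak caller, its threshold and the use of the input libraries are not given in the sources used here. Each list was deposited with positions, strand, annotation class, nearest gene and 1 score per peak. The authors' score has no stated scale. It takes 223 distinct values in control, 253 in TBP, 214 in TCP and 44 in TIP, with a different lowest value in each list, so it was used to rank or filter peaks within a list. An alternative fixed in advance, a common minimum at the control median, sets scores of different lists against one another and is given with that reservation. Peak widths were multiples of 25 bp for 97.1% to 98.2% of peaks, and 1.15% to 2.25% spanned over 500 bp of genome. Whether these wide peaks cross introns was not examined.

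The plan was to count genes as the lists name them. After the lists had been seen this was changed, because their gene column names the nearest gene, which is often not the gene that holds the peak, for example where a 3′ UTR peak lies near the start of a gene on the other strand. The gene holding the peak on its strand was used instead. It was taken from the lists' own exon annotation (45.1% of 20732 peaks), else from the nearest gene if the peak lay inside it on the same strand (37.7%), else from a single RefSeq gene over the peak (16.0%; GRCm38.p6 gene spans). This placed 98.8% of peaks, and the gene differed from the nearest-gene column for 22.8%. A second change followed a first complete run: a microRNA nested in another gene had appeared among the genes named for TIP, and small RNA genes were then passed over in the first steps. It moved 5 peaks, took the genes with a peak in any list from 4325 to 4320, the genes gained in TBP from 1089 to 1087 and those gained in TIP from 333 to 332, and put Smg5 among the genes named for TIP. Counts under both earlier rules were kept as alternatives.

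Peaks were compared with bedtools 2.31.1, with at least 1 bp of overlap on the same strand. A gene was called gained if it had a peak in the compound's list and none in control, and lost in the reverse case. Shares have exact Clopper-Pearson 95% intervals. Peaks and genes are not independent molecules or cultures, so intervals cover counting error only. Differences between compounds were taken over the same genes, with a normal-approximation interval for paired shares. The presence model gives each gene a normally distributed detection strength and each library a sensitivity, is truncated at genes with no peak, and was fitted to the 15 presence patterns of the 4 lists; ranges come from 10000 draws. Each library is a single compound, so its sensitivity also holds any overall effect of that compound. The model was tested on simulated data, where the largest error of a library effect was 0.028 on the logit scale. There, 200 genes added to a pattern took it to 512, above the upper end of 438. The simulation had 6192 genes, a smaller spread of detection strength than fitted here and 325 genes expected in that pattern. It does not show that a smaller excess would be found in these lists. The overlap step recovered 600 of 600 planted shared peaks.

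Before the data were examined, 20 lists with 577 genes were fixed, of which 565 matched a RefSeq symbol. Percentiles were computed for the 18 lists with at least 3 members with a peak, by 10000 random sets drawn from the 4320 genes. Sets were matched on the number of libraries with a peak for presence and on 10 strata of gene length for gained and lost genes. The list of mitochondrially encoded genes had no peak, and 3 of its 15 members matched RefSeq symbols, so it rests on the absence of peaks on that chromosome. Named genes follow a rule fixed in advance: per compound, the 8 gained genes ranking highest by strongest peak in the compound's list and the 8 lost genes ranking highest in control, without unnamed genes and pseudogenes; the 10 genes in all 4 lists with the best mean rank; and up to 4 members per list, those gained or lost with the most compounds. Ties in rank, which the rule left open for the gained and lost genes, were taken in alphabetical order. Not all of those members are told here. Which of them are told, and further members of the lists and of shared sets, was decided after their values were seen. Results for a few genes are not reported here.

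Alternatives fixed in advance were a reciprocal overlap of 50%, peaks extended by 200 bp, peaks at or above their list's median score, equal list length (the 3034 best-scored peaks of each list, ties broken at random with a fixed seed), peaks within 100 bp merged, the common score minimum, and shares by covered length. Leaving out peaks outside exons and UTRs removed 0 peaks. The nearest-gene column, leaving out peaks over 500 bp (also for shares by covered length), genes with at least 2 peaks, small RNA genes as hosts, and random sets matched on control presence as well as gene length were added after seeing the data. A planned count of m6A consensus motifs was not run, since no genome sequence was used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.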

Results

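The study mapped N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, in RAW264.7 cells, a mouse macrophage line, by immunoprecipitation of RNA fragments with an m6A antibody followed by sequencing (MeRIP-seq). Cells were left untreated or were given 100 µM of TBP, TCP or TIP for 24 h; these are the labels' own abbreviations and are not spelled out in them. Each of the 4 conditions has 1 immunoprecipitated library and 1 RNA input library. The values are the authors' peak lists of the 4 immunoprecipitated libraries; the 4 input libraries were not analysed here. With 1 library per condition there is no replicate, so no p-value is given, and every 95% interval (exact Clopper-Pearson unless said otherwise) covers counting error only, not the spread between cultures. The lists carry no read counts, so the depth behind a peak is unknown. A peak missing from a list means that none was called there, not that the transcript was unmethylated. Coordinates are on GRCm38 (mm10).

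The design asks how m6A-marked RNA differs between untreated cells and cells given each compound. The control list held 4432 peaks in 2480 genes. The TBP list held 6285 peaks in 3140 genes, a ratio to control of 1.42 for peaks and 1.27 for genes. The TCP list was the longest, with 6981 peaks in 3397 genes, ratios of 1.58 and 1.37. The TIP list was the shortest, with 3034 peaks in 1797 genes, ratios of 0.685 and 0.725. In all, 4320 genes had a peak in at least 1 list and 1286 had one in all 4. The median peak spanned 50 bp in each list. The authors' score per peak had a different floor in each list, 8.59 in control, 8.56 in TBP, 8.73 in TCP and 10.7 in TIP. When a single score minimum was set at the control median of 8.95, the order of TIP and control turned: TIP kept its 3034 peaks and control kept 2302, although it is not known whether scores share a scale across lists.

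**Figure D1:**
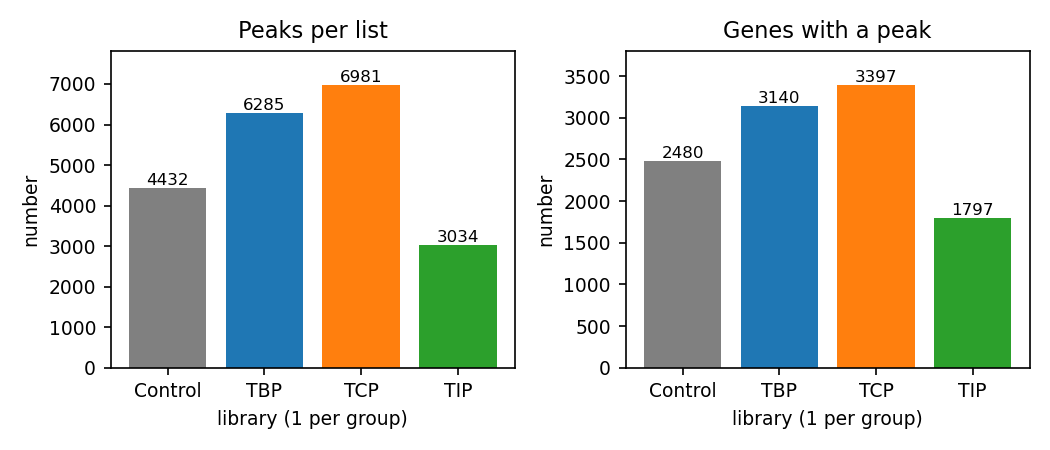
Number of peaks (left) and of genes with a peak (right) in each list, with 1 library per bar and no error bar because there is no replicate. TCP has the most peaks (6981) and TIP the fewest (3034), against 4432 in control.

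By number, most peaks of each list lay in 3′ UTRs and in exons outside UTRs. In control, 50.9% of peaks (49.4 to 52.4) were annotated to 3′ UTRs, 45.0% (43.5 to 46.4) to exons outside UTRs and 4.13% (3.56 to 4.76) to 5′ UTRs. The 3′ UTR share was 50.7% (49.4 to 51.9) in TBP, 48.5% (47.3 to 49.7) in TCP and 48.8% (47.0 to 50.6) in TIP. The exon share was 45.5% in TBP, 47.6% (46.5 to 48.8) in TCP and 47.7% (45.9 to 49.5) in TIP. The 5′ UTR share lay between 3.49% and 4.13% in the 4 lists. By covered length, of which the few peaks spanning over 500 bp of genome hold 33.3% in control, 48.9% in TBP, 55.7% in TCP and 41.0% in TIP, the lists differed more. The shares were a 3′ UTR share of 45.7% in control, 37.6% in TBP, 33.2% in TCP and 34.5% in TIP, an exon share of 45.2% in control and 61.4% in TIP, and a 5′ UTR share of 9.01% in control and 17.3% in TBP. With those peaks left out, a choice made after seeing the data, the 3′ UTR share of length was 52.5%, 52.0%, 49.6% and 48.2% in control, TBP, TCP and TIP, and the 5′ UTR share was at most 3.60%. No peak in any list lay on the mitochondrial chromosome, and 0 of 31 marker genes of other cell types had a peak.

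A set of 1286 genes had a peak in every list. By mean rank of the strongest peak, the leading 10 of them were Neat1, Itga4, Eif4g1, Ahnak, Mcl1, Hspa5, Spred1, St8sia4, Tlr2 and H2ax. Neat1, a nuclear long non-coding RNA, had 5 peaks in control, 7 in TBP, 3 in TCP and 6 in TIP, with its strongest control peak in an exon at chromosome 19, 5843883 to 5844032. Itga4, which encodes the integrin alpha 4 chain, had 12, 12, 11 and 9 peaks in control, TBP, TCP and TIP. Its 3′ UTR peak at chromosome 2, 79326746 to 79326995, ranked 1 in the control list. Ahnak, which encodes a very large scaffold protein, had 31, 32, 33 and 34 peaks in the same order. Mcl1, an anti-apoptotic member of the Bcl-2 family, had 2, 3, 2 and 3, and Tlr2, a Toll-like receptor for bacterial lipoproteins, had 8, 11, 7 and 6. Itga4, Eif4g1 and Spred1 were placed here by the gene that holds the peak, where the authors' nearest-gene column names another gene.

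After TBP, 1087 genes had a peak that had none in control (gained), 34.6% (33.0 to 36.3) of the TBP genes. In turn, 427 control genes had no TBP peak (lost), 17.2% (15.8 to 18.8) of the control genes. The gained gene with the highest-ranked TBP peak was Foxo3, a forkhead transcription factor, with 2 TBP peaks and 0 in control. Its strongest peak ranked 60 of 6285 and lay in an exon at chromosome 10, 42196563 to 42196712, minus strand. Next came Xpo1, the main nuclear export receptor for proteins, with 3 TBP peaks (exon, chromosome 11, 23284274 to 23284565, rank 260). They were followed by Phb2 (1 TBP peak), a prohibitin of the mitochondrial inner membrane, Colgalt1 (2), a collagen galactosyltransferase, Bicd2 (2), a dynein adaptor, Fut10 (2), Carm1 (1), an arginine methyltransferase, and Cnbp (3), a nucleic acid-binding zinc finger protein. The lost genes with the highest-ranked control peaks were Malat1, a nuclear long non-coding RNA, with 3 peaks in control and 0 in TBP, and Pabpc1, the cytoplasmic poly(A)-binding protein, with 2 and 0. Malat1's control peak at chromosome 19, 5799215 to 5799264, ranked 43, and Pabpc1's at chromosome 15, 36605892 to 36608342, ranked 129. Nfkbia, the inhibitor of NF-κB, had 1 peak in control, in its 3′ UTR at chromosome 12, 55489910 to 55489934 (rank 194), and 0 in TBP. Also lost were Klhdc3, Actb (cytoplasmic beta-actin), Cap1 (an actin regulator), Smap2 and H1f3 (a linker histone), with 1, 2, 3, 2 and 1 control peaks. For Phb2, Klhdc3 and Smap2 the authors' nearest-gene column names another gene.

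At the level of peaks, 3771 TBP peaks, 60.0% (58.8 to 61.2), did not overlap a control peak by at least 1 bp, and 1892 control peaks, 42.7% (41.2 to 44.2), did not overlap a TBP peak. With the 3034 best-scored peaks of each list, the TBP counts were 484 genes gained and 504 lost. Gained minus lost genes is the difference in genes between the lists, so it follows list length, and its change at equal list length is not a separate result.

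After TCP, 1317 genes were gained, 38.8% (37.1 to 40.4) of the TCP genes, and 400 were lost, 16.1% (14.7 to 17.6) of the control genes. Foxo3 again led the gained genes, with 3 TCP peaks and 0 in control. Its strongest TCP peak, at chromosome 10, 42196613 to 42196712, ranked 91 of 6981. Arhgdia had 4 TCP peaks (strongest in an exon at chromosome 11, 120579279 to 120579303, rank 99). The others were Gpsm2, a spindle orientation protein, Mrps27, a mitochondrial ribosomal protein, Birc5 (survivin), Cipc, a circadian repressor, Rev1, a translesion DNA polymerase, and Fut10, with 1, 1, 1, 1, 2 and 3 TCP peaks. The lost genes were led by Tmsb4x, thymosin beta 4, which binds monomeric actin. It had 1 control peak in its 3′ UTR at chromosome X, 167207368 to 167207467 (rank 23), 2 in TBP and 0 in TCP. Malat1, Pabpc1, Nfkbia, Actb and H1f3 were lost in TCP as in TBP. Cd164, a sialomucin, and Rpl4, a protein of the large ribosomal subunit, were the other two, with 1 and 2 control peaks and 0 in TCP. For Gpsm2, Mrps27, Birc5 and Rpl4 the authors' nearest-gene column names another gene.

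Of the TCP peaks, 4509, or 64.6% (63.5 to 65.7), did not overlap a control peak, and 1963 control peaks, 44.3% (42.8 to 45.8), did not overlap a TCP peak. At equal list length 514 genes were gained and 530 lost.

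After TIP the counts went the other way, with 332 genes gained, 18.5% (16.7 to 20.3) of the TIP genes, and 1015 lost, 40.9% (39.0 to 42.9) of the control genes. Tmsb4x had the highest-ranked control peak of the genes lost in TIP. Rsrp1, an arginine- and serine-rich protein, had 2 control peaks (3′ UTR, chromosome 4, 134927048 to 134927197, rank 33) and 0 in TIP. Pdia6, a protein disulfide isomerase of the endoplasmic reticulum, had 2 peaks in control, 3 in TBP, 6 in TCP and 0 in TIP. Naa15, a subunit of the N-terminal acetyltransferase NatA, had 5, 7, 6 and 0 in the same order, with its strongest control peak in the 3′ UTR at chromosome 3, 51472781 to 51472805. Cpsf6, a pre-mRNA cleavage factor, had 2, 3, 1 and 0, and Nfya, the alpha subunit of the CCAAT-binding factor NF-Y, had 2, 5, 4 and 0. Pabpc1 and Nfkbia completed the 8 and were without a peak in all 3 compound lists. The gained genes with the highest-ranked TIP peaks were Arhgdia, Birc5, Cipc, Khdc4, Mrps27, Nav2, Rabgef1 and Smg5. These shared rank 16 with 301 tied TIP peaks and were taken in alphabetical order; 7 of the 8 had 1 TIP peak and Khdc4 had 2. For Naa15, Birc5 and Mrps27 the authors' nearest-gene column names another gene.

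Of the TIP peaks, 1462, or 48.2% (46.4 to 50), did not overlap a control peak, and 2869 control peaks, 64.7% (63.3 to 66.1), did not overlap a TIP peak. At equal list length 475 genes were gained and 559 lost.

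**Figure D2:**
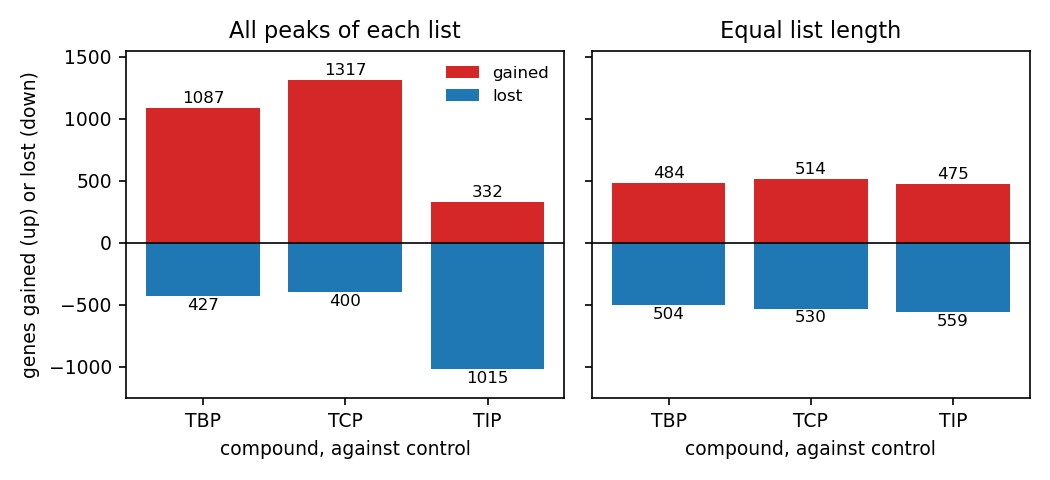
Genes gained (red, upward) and lost (blue, downward) against control for each compound, counted over all peaks (left) and over the 3034 best-scored peaks of each list (right), with 1 library per condition and no error bars. The counts of 1087 and 427 for TBP and of 332 and 1015 for TIP become 484 and 504, and 475 and 559, at equal list length.

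The 3 compounds were given at the same dose and time, so their lists can be set against one another. TBP and TCP kept similar shares of the 2480 control genes, 82.8% and 83.9%, a difference of 1.09 percentage points (TCP minus TBP, 95% interval −0.570 to 2.75, normal approximation over paired genes). TIP kept 59.1%, a difference of −23.7 points to TBP (−25.8 to −21.7) and of −24.8 points to TCP (−26.8 to −22.8). At equal list length the control list is cut too and held 1881 genes, of which TBP kept 73.2%, TCP 71.8% and TIP 70.3%. The difference of TIP to TBP was then −2.92 points (−5.20 to −0.652). The intervals of the other kept differences at equal length included 0, with TCP minus TBP at −1.38 points (−3.58 to 0.817) and TIP minus TCP at −1.54 points (−3.71 to 0.630). None of these intervals covers the random choice among tied peaks or the spread between cultures, so they do not separate the compounds. Of the 1840 genes without a control peak and with a peak in at least 1 compound list, TCP gained 71.6% and TBP 59.1%, a difference of 12.5 points (8.93 to 16.1). Of the same 1840, TIP gained 18.0%, a difference of −41.0 points to TBP (−43.9 to −38.2) and of −53.5 points to TCP (−56.3 to −50.8). At equal list length there were 997 such genes. Over these, the difference of TCP to TBP was 3.01 points (−1.75 to 7.76). The differences of TIP were −0.903 points to TBP (−5.76 to 3.96) and −3.91 points to TCP (−8.64 to 0.821). By overlap of peaks, 45.5% (44.3 to 46.7) of TCP peaks overlapped a TBP peak, 53.6% (51.8 to 55.4) of TIP peaks overlapped a TBP peak and 56.2% (54.4 to 58.0) of TIP peaks overlapped a TCP peak. The order turned at equal list length, with 54.4% for TCP over TBP, 50% for TIP over TBP and 51.6% for TIP over TCP. The gene sets of TBP and TCP shared 2471 of 4066 genes (60.8%, 59.3 to 62.3). TIP shared 1543 of 3394 with TBP (45.5%) and 1603 of 3591 with TCP (44.6%). As a share of the shorter list the order was the reverse: 78.7% for TBP and TCP, 85.9% for TBP and TIP and 89.2% for TCP and TIP.

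TBP and TCP gained 625 genes in common, among them Foxo3, Fut10, Carm1, Arhgdia and Birc5, and lost 193 in common, among them Malat1, Pabpc1, Nfkbia, Actb and H1f3. Independent sets of these sizes would share 331 and 39.5 among all 4320 genes. Among the 1840 genes gained with at least 1 compound and the 2480 control genes they would share 778 and 68.9. The 1840 are selected by having been gained, which raises the 778, so lying below it is no sign of little sharing. The gained count thus lies above or below independence with the set chosen. A model with 1 detection strength per gene and 1 sensitivity per library, which takes up any overall effect of a compound, gave 641 (central 95% of draws 595 to 687) and 195 (169 to 223). TBP and TIP gained 193 genes in common and lost 312, below the model's 207 to 266 and 326 to 397. Independent sets among the same 1840 and 2480 genes gave 196 and 175, with the same limit for the gained genes. At equal list length the gained count, 174, stayed below its range (176 to 229) and the lost count, 293, lay inside (287 to 353). With peaks at or above the median score the gained count, 150, lay inside (140 to 188) and the lost count, 198, below (200 to 256). TCP and TIP gained 232 and lost 306, inside its ranges of 224 to 284 and 278 to 344, where independent sets among the same genes gave 238 and 164. Genes with a peak in all 3 compound lists and none in control numbered 154, fewer than the model's 163 to 216. Of these, 8 had 2 or more peaks in each compound list, and Foxo3 was 1 of them with 2, 3 and 2. Genes with a peak in control alone numbered 163, inside 152 to 202, and included Pabpc1, Nfkbia, Actb and H1f3. The 3 comparisons use the same control library, which cannot be split, so part of any overlap between them can come from it. Of all 15 presence patterns, control with TIP (30 genes, range 11 to 28) lay above the model, and control with TCP (149, range 159 to 211) and the 3 compounds together lay below it. All 3 counts lay inside at equal list length (82 in 67 to 102, 81 in 78 to 115 and 108 in 100 to 143), where control with TBP (115, range 77 to 114) lay above instead. With peaks at or above the median score, control with TIP (12, range 5 to 18) lay inside and control with TCP (90, range 96 to 137) below.

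**Figure D3:**
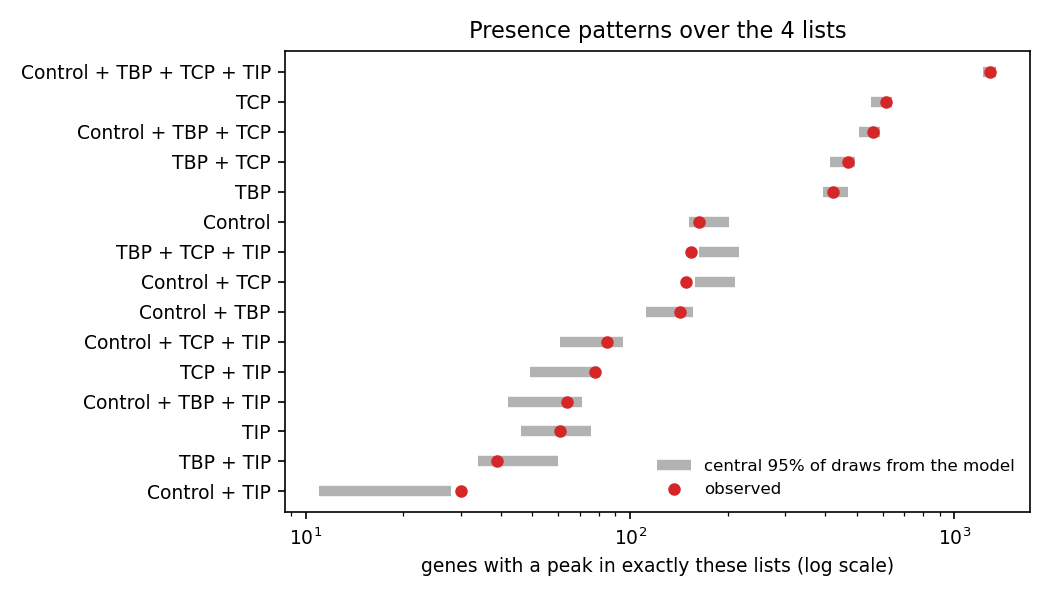
Number of genes (log scale) with a peak in exactly the lists named on the vertical axis. Red points are the observed counts and grey bars the central 95% of draws from the model with 1 sensitivity per library; the pattern of TBP, TCP and TIP without control (154 genes) lies left of its bar of 163 to 216, and the pattern of control with TIP (30) lies right of its bar of 11 to 28.

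Gene groups fixed before the data were examined were compared by the number of members with a peak. Percentiles are among 10000 random gene sets of the same size and describe these libraries. In all, 180 such percentiles were computed over 18 groups, and 8 of them lay in the outer 5%, against a nominal 9 by chance. Some counts are too small to reach an end of the scale: 0 cytokines gained in TIP lay at percentile 31.7. The number by chance may thus be below 9, so the 8 neither show nor exclude an excess of extreme values. For gained and lost genes a second percentile, chosen after the first were seen, matches the random sets on control presence too. Of 108 such percentiles, 6 lay in the outer 5%, against a nominal 5.4 by chance, with the same limit.

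Transcripts of the m6A machinery itself carried peaks in every list. Of 12 genes of the methyltransferase group, 6 had a peak in control, 7 in TBP, 8 in TCP and 6 in TIP. Rbm15, an adaptor of the methyltransferase complex, had 5, 8, 9 and 3 peaks in control, TBP, TCP and TIP, and Virma, its scaffold, had 2, 4, 5 and 2. Pcif1, which methylates adenosines next to the cap, had 0 in control and 1 in each compound list. Of 16 demethylases and readers, 8, 8, 9 and 7 had a peak in the same order of lists. The readers Ythdf2 (4, 7, 6 and 4 peaks) and Ythdf3 (6, 4, 6 and 4) had peaks in all 4, and the demethylase Fto had 1 control peak and 0 elsewhere. No percentile of these groups lay in the outer 5%.

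Of 30 macrophage identity genes, 13 had a peak in control, 16 in TBP, 12 in TCP and 10 in TIP. Csf1r, the receptor for macrophage colony-stimulating factor, had 4, 4, 5 and 4 peaks, and Mpeg1, perforin-2, had 8, 10, 10 and 11. Lyz2, Trem2 and Cd68 had control peaks (2, 2 and 1) and TBP peaks (1 each) but 0 in TCP and in TIP. Others went the other way in TCP: Irf8 and Ptprc had 0, 1, 3 and 0 peaks each, and Cx3cr1 had 2, 6, 9 and 3. The count in TCP, 12 against a random mean of 15.2, lay at percentile 1.61. Random sets for presence were matched on the number of libraries with a peak, so high counts in control and TBP (percentiles 80.3 and 87.9) can lower it. Matched on control presence, TCP lost 3 of the group (percentile 54.2) and gained 2 (percentile 11.3). Of 30 cytokines and chemokines, 5 had a peak in control, 3 in TBP, 5 in TCP and 2 in TIP. Tnf had 1 peak in each list, and the chemokine Ccl9 had 1 in control alone. Of 40 genes of Toll-like receptor and NF-κB signalling, 13, 15, 14 and 10 had a peak. Tlr7, an endosomal receptor for RNA, had 9, 15, 12 and 5 peaks, and Tlr4, the receptor for lipopolysaccharide, had 2, 5, 3 and 1.

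Among 30 JAK-STAT and interferon genes, 6 had a peak in control, 9 in TBP, 10 in TCP and 3 in TIP. The interferon receptor chain Ifnar2 had 3, 5, 6 and 4 peaks, and Socs5, a suppressor of cytokine signalling, had 0, 2, 1 and 0. Of 30 MAPK and AP-1 genes, 8, 10, 11 and 6 had a peak, with Jun at 2, 3, 2 and 2 and the kinase Map3k3 at 0, 1, 3 and 0. Of 30 genes of the Nrf2 and oxidative stress group, 9, 12, 10 and 7 had a peak. Nfe2l2, which encodes Nrf2, had 4, 5, 6 and 3 peaks, Keap1, its repressor, had 4, 5, 4 and 3, and Txnrd1, thioredoxin reductase, had 0 in control and 1 with each compound. Of 25 genes of the endoplasmic reticulum and integrated stress responses, 13, 14, 15 and 10 had a peak. Atf4, the central transcription factor of the integrated stress response, had 0 in control and 1 with each compound. Eif2ak3, the kinase PERK, had 0, 3, 3 and 0, and Asns, asparagine synthetase, had 2 in control and 0 elsewhere. Of 32 p53 and apoptosis genes, 11, 11, 13 and 9 had a peak, with Bax at 1, 0, 0 and 1 (its TIP peak has another gene in the nearest-gene column). None of the percentiles of these 5 groups, of the cytokine group or of the Toll-like receptor group lay in the outer 5%.

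Of 30 autophagy and lysosome genes, 8 had a peak in control, 9 in TBP, 8 in TCP and 5 in TIP, among them Mtor with 1, 1, 2 and 0. Of 32 xenobiotic and nuclear receptor genes, 1 had a peak in control, 4 in TBP, 5 in TCP and 3 in TIP. Tiparp, a target of the aryl hydrocarbon receptor, had 2, 2, 4 and 4 peaks, and Nr3c1, the glucocorticoid receptor, had 0, 1, 3 and 1. Of 30 lipid and cholesterol genes, 7, 12, 10 and 9 had a peak. Abca1, the cholesterol exporter, had 0, 2, 2 and 1 peaks, and Sqle, squalene epoxidase, had 1, 4, 3 and 2. No percentile of these 3 groups lay in the outer 5%. Of 31 cell cycle genes, 7, 9, 9 and 7 had a peak, led by Mki67 with 25, 27, 34 and 24. No cell cycle gene was lost in TIP, against a random mean of 2.90 (percentile 1.66; 1.04 matched on control presence).

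Chromatin and transcription regulators were the group with the largest share of members in the lists, with 27 of 40 in control, 30 in TBP, 31 in TCP and 23 in TIP. The histone methyltransferase Kmt2d had 10, 16, 16 and 3 peaks, Arid1a, a subunit of the BAF remodelling complex, had 6, 10, 10 and 5, and Tet2, a DNA demethylation enzyme, had 0, 3, 3 and 0. TCP gained 4 of the group against a random mean of 9.55 (percentile 1.3). Of the 32 members with a peak in any list, only 5 had none in control, and matched on control presence the percentile was 53.6. Of the 27 with a control peak TCP lost 0 (percentile 5.29; 2.03 matched on control presence) and TIP lost 5 (percentile 19.0; 2.07 matched). Of 30 phagocytosis and cytoskeleton genes, 18 had a peak in control, 17 in TBP, 17 in TCP and 11 in TIP. TCP lost 6 of them against a random mean of 1.75 (percentile 99.7), TBP lost 5 (percentile 97.3) and TIP lost 9 (percentile 95.3). Matched on control presence these percentiles were 98.9, 93.1 and 84.5. The formin Diaph1 and vimentin (Vim) had 1 control peak each and 0 with every compound. For the strongest peaks of Cs, Pkm and Mtor, of other groups, the nearest-gene column names another gene.

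Of 30 genes of glycolysis and mitochondrial energy supply, 8 had a peak in control, 14 in TBP, 16 in TCP and 9 in TIP. TIP gained 6 against a random mean of 1.75 (percentile 99.7; 98.4 matched on control presence), among them Cs, citrate synthase, with 0, 2, 3 and 1 peaks, Atp5a1, of the ATP synthase, with 0, 2, 1 and 1, and Pkm, pyruvate kinase, with 0, 0, 2 and 1. Restricted to peaks at or above the median score of their list, TIP gained 2 of this group, and at equal list length it gained 6. Of 33 ribosomal protein genes, 11 had a peak in control, 10 in TBP, 6 in TCP and 6 in TIP. The TCP count lay at percentile 0.015 (random mean 12.0) and the control count at percentile 99.0 (random mean 6.98). TCP lost 7 of these genes against a random mean of 2.64 (percentile 99.5; 98.9 matched on control presence), 4 when peaks below the median score were left out and 9 at equal list length. TIP lost 7 as well (percentile 91.6; 84.1 matched on control presence) and TBP lost 4 (percentile 89.2; 82.7 matched). Rps9 had 1 control peak and 0 elsewhere, and Rplp0 had 1, 1, 0 and 0.

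**Figure D4:**
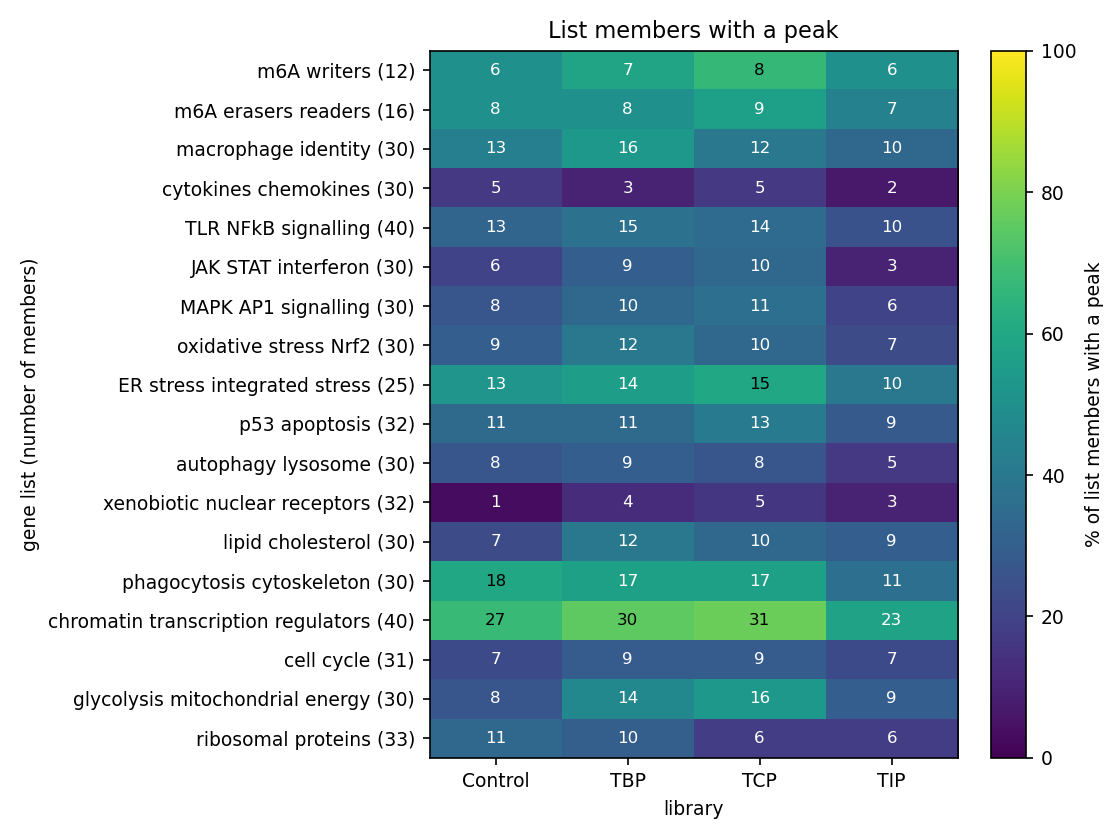
Members of each gene group (rows, with group size in parentheses) that have a peak in each library (columns). Numbers are genes and colours the percent of the group; chromatin and transcription regulators run from 23 to 31 of 40, and ribosomal proteins from 11 of 33 in control to 6 in TCP and 6 in TIP.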

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

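The rank and model tests were set before their results were computed but after the list lengths were known; the tests on genes outside the fixed groups and those matched on control presence were chosen after the group percentiles had been seen. The rank tests met the bound set in advance for a difference in sensitivity (over 0.60 of pairs), and the ribosomal test the bound for chance (percentile 10 or higher), but after their values were seen both were set aside as undecided, for the reasons given with them. The number of peaks as a ratio to control was 1.42 in TBP and 1.58 in TCP but 0.685 in TIP. It stands out because the lists of compounds given at the same dose and time lay on opposite sides of control in length. The difference was not tested, since each condition has 1 library.

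The first pattern is the list length, with the genes gained in TBP and TCP and lost in TIP. If libraries differed in sensitivity, genes found in a single list would carry its weaker peaks. A control gene kept in TIP outranked one lost in TIP, by strongest control score, in 0.811 of pairs (0.793 to 0.827, bootstrap over genes), and a TBP or TCP gene also in control outranked a gained one in 0.807 and 0.806 of pairs. The directions that sensitivity does not call for gave 0.769 (lost in TBP), 0.741 (lost in TCP) and 0.717 (gained in TIP), and genes in both lists have more peaks, so the rank test does not decide. A global change in m6A and a difference in sensitivity, depth or antibody yield cannot be told apart, because each compound has 1 library, and the effect of the compounds stays open and untested. The input libraries were not analysed, so a change in the amount of a transcript was not separated from a change in its m6A. The calling threshold of each list is not known, so a difference in threshold was not separated either.

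The second pattern is the sharing of genes between compounds. The genes gained in both TBP and TCP, 625, lay inside the 595 to 687 of the model with 1 sensitivity per library, and the 163 genes with a peak in control alone lay inside 152 to 202; both fits are at the level of genes, and an overall effect of a compound is taken up by its library's sensitivity, so these counts do not exclude one. The 154 genes in all 3 compound lists and not in control lay below its range of 163 to 216, which argues against that model as a full account. An overall gain with the compounds is taken up by the sensitivities, so this count does not argue against a shared gain. That count lay inside the range at equal list length, where it was 108 (100 to 143), and among peaks at or above the median score, 123 (110 to 154). Over regions in place of genes all of these counts lay below the model, with 213 regions in all 3 compound lists and not in control against 317 to 388, 1131 gained in both TBP and TCP against 1238 to 1373, and 1071 in control alone against 1116 to 1244. Other region counts lay above it, with 1244 in all 4 lists against 1029 to 1152, 759 in TIP alone against 544 to 636, and 2952 in TCP alone against 2722 to 2908. The model thus describes regions poorly, and the low counts are not read as little sharing.

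The third pattern is the low number of ribosomal protein genes with a peak in TCP, 6 against a random mean of 12.0. A chance pick among 180 percentiles is a candidate explanation, and 47 ribosomal protein genes outside the group lay at percentile 13.83 in TCP. Of these, 11 had a peak in any list and 5 in control, of which TCP lost 4, percentile 98.4 matched on control presence, so chance is neither shown nor excluded. The loss was not particular to TCP: of the same 5, TBP lost 4 (percentile 99.3) and TIP lost 5 (percentile 98.7). Fewer peaks on abundant transcripts of any kind in the TCP library is another candidate explanation. For it, 35 genes that code for no ribosomal protein were taken as abundant, but their abundance was not measured here. Of these, 15 had a peak in TCP against a random mean of 19.9, percentile 0.33. Their losses in TCP, 5 of 18, lay at percentile 87.3 (74.2 matched on control presence). The control count was itself high, at percentile 99.0 in the group, 98.6 for the ribosomal protein genes outside it and 97.2 for the transcripts taken as abundant. Random sets for presence were matched on the number of libraries with a peak, so a high control count can lower the percentiles of other lists, the 0.33 in TCP included. The transcripts taken as abundant also had a high count in TIP, at percentile 96.9. In the group TBP lay at percentile 37.2 and TIP at 94.4. Both accounts stay open, and a specific effect of TCP on ribosomal protein transcripts was not separated from them or from the high control count.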

How the results depend on the processing

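No paired analysis was possible because each condition has 1 library and the labels give no replicate numbers; for the same reason no replicate could be left out. The motif alternatives were not run. Depth is unknown and limits every absence of a peak. Over all alternatives, 97 values stayed within 1.5 times the reported count or within the interval of the reported share, and 58 did not; for the gene groups it was 355 and 125 counts. Lost exceeded gained for TIP in all alternatives run on gained and lost sets. Outside equal list length, gained exceeded lost for TBP and TCP in these alternatives. At equal list length the balance of genes turned for both, and that balance follows list length. For TBP peaks gained still exceeded lost there. Of 3034 peaks each, 1703 TBP peaks overlapped a control peak and 1725 control peaks overlapped a TBP peak. The gained and lost sets were not recomputed for merged peaks or the common score minimum. Where the alternative removes peaks or widens overlap, the counts change by its construction; beyond that the cause was not tested.

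With the score at or above the control median, peaks were 2302 in control, 3422 in TBP and 4644 in TCP, and TIP stayed at 3034. With peaks extended by 200 bp, gained peaks were 2394 for TBP, 2924 for TCP and 766 for TIP, and lost peaks 925 for TBP and 925 for TCP. With peaks at or above their list's median score, gained peaks were 1862, 2253 and 674 for TBP, TCP and TIP, and lost peaks 742, 836 and 1411. Genes with a peak were then 1501 in control, 2054 in TBP, 2195 in TCP and 1063 in TIP, and 243 were lost in TBP. At equal list length, gained peaks were 1331 for TBP and 1413 for TCP, lost peaks 1567 for TIP, genes with a peak 1861 in TBP and 1865 in TCP, genes gained 484 and 514, and genes lost in TIP 559. Counting genes with at least 2 peaks, chosen after seeing the data, gave 220, 285 and 27 gained and 32, 44 and 178 lost for TBP, TCP and TIP.

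The share of TCP peaks over a TBP peak was 29.2% with 50% reciprocal overlap, 69.0% extended, 51.3% at or above the median score and 54.4% at equal length. For TIP peaks over TBP these were 31.1%, 79.8%, 66.4% and 50%, and for TIP over TCP 31.7%, 83.6%, 67.1% and 51.6%. By covered length, the 3′ UTR share was 45.7% in control, 37.6% in TBP, 33.2% in TCP and 34.5% in TIP, the exon share 51.7% in TCP and 61.4% in TIP, and the 5′ UTR share 9.01%, 17.3% and 15.1% in control, TBP and TCP. With peaks over 500 bp also left out, chosen after seeing the data, the 3′ UTR share of length was 52.5% in control and 52.0% in TBP, so the wide peaks carry most of the difference. In control at or above the median score, the 3′ UTR share was 53.1% and the 5′ UTR share 3.34%.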

Other observations

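Among the 154 genes with a peak in each of the 3 compound lists and none in control, those with the most peaks, chosen after their values were seen, were led by Dicer1, the nuclease that matures microRNAs, with 6 peaks in TBP, 4 in TCP and 1 in TIP. Gins3, a subunit of the replicative helicase, had 2, 5 and 2, Mdn1, a ribosome assembly ATPase, had 2, 4 and 3, and Sec62, of the endoplasmic reticulum translocon, had 4, 3 and 2. Baz1a, Dido1, Foxo3, Fryl, Parg and Rrbp1 followed, with 4, 3 and 1, 4, 2 and 2, 2, 3 and 2, 2, 4 and 1, 3, 3 and 1, and 3, 3 and 1. Among genes with a peak in control alone, Atpif1, the inhibitor of the mitochondrial ATP synthase, had 3, and Actb, Asns, Eef1d, Fcrl1, Pabpc1, Paics, Sdf4 and Srek1ip1 had 2 each. Peaks in control, TBP and TCP but not TIP were found for 560 genes.

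Outside the fixed groups, after the group percentiles had been seen, 96 respiratory chain and tricarboxylic acid cycle genes were examined for the gain of energy genes in TIP. Of these, 28 had a peak in any list and 3 were gained in TIP against a random mean of 2.15 (percentile 73.61, or 66.2 matched on control presence). A gain in TIP beyond random sets was thus not seen for these genes. Only 14 of the 28 had no control peak, so a small gain could be missed. The set does not cover glycolysis, so glycolysis members of the fixed group such as Pkm were not examined by it. A chance pick is a possible explanation of the 6 in the fixed group. In TCP the respiratory chain and tricarboxylic acid cycle genes lost 7 of the 14 with a control peak, against a random mean of 3.17 (percentile 98.0, or 99.1 matched on control presence). The ribosomal protein genes outside the group had 5 with a peak in control against 2.11 (percentile 98.6) and lost 4 in TBP (percentile 97.9). Matched on control presence, their losses lay at percentile 99.3 in TBP (4 of 5), 98.4 in TCP (4 of 5) and 98.7 in TIP (5 of 5). The transcripts taken as abundant gained 2 in TCP against 7.56 (percentile 0.34, or 2.43 matched on control presence). They lost 5 of 18 there (percentile 87.3, or 74.2 matched). In these 3 sets, 5 of 30 percentiles lay in the outer 5%, against a nominal 1.5 by chance. The sets were chosen after seeing the data and overlap in what they test.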
